A study of Mus musculus with 72 samples.

How the data were processed

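Gene expression was measured by mRNA sequencing in 72 libraries from the brains of C57BL/6 mice aged 7 months. Stroke was induced by occluding the middle cerebral artery on 1 side for 1 h, and a section from the middle of the cerebrum on the occluded side was taken. The libraries cover 6 stages, namely sham, 1 h of ischemia without reperfusion, and 3, 12, 24 and 72 h of reperfusion. Each stage was crossed with 4 feeding regimens, namely ad libitum feeding (AL), every-other-day fasting with 24 h without food (EOD), 12 h of daily fasting (IF12) and 16 h of daily fasting (IF16), and daily fasting lasted 4 months. Each of the 24 groups has 3 libraries, and each library's stage, regimen and replicate number came from its title in the labels. For replicate 1 of the EOD sham group the source name gives the stage in place of the tissue, without conflict with its title. The labels do not say that the 3 libraries of a group came from separate animals, so p-values set differences against the spread between these samples, which may be technical.

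The deposited table holds whole-number counts per gene and, beside them, FPKM values per gene and library. Per the submitters' processing notes, CASAVA, TopHat2 and DESeq2 were used by the authors with the GRCm38/mm10 build, while the versions, the annotation release, the counting rule and its use of strand are not given in the sources used here. RNA was extracted from frozen tissue and samples had an RNA integrity number above 7, per the labels' protocols. The deposited FPKM values equalled the deposited counts divided by gene length and by the library's total, with a largest relative deviation of 7.31e-09 over 839188 values, so they hold no further normalization, and 28459 genes gave a length this way. The tests below used the counts as deposited, and the FPKM values served only to obtain gene lengths. The table has 35275 Ensembl gene identifiers, of which 6816 had no read in any library. A symbol from the GENCODE M21 annotation of GRCm38 was found for 34490 identifiers and not for the other 785, and coordinates were taken from that annotation. Reads from near-identical genes, such as Hspa1a and Hspa1b or the hemoglobin genes, and from overlapping or antisense genes cannot be told apart without the counting rule, so values of such genes are uncertain.

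Library totals ran from 16735707 to 24763161 counts. Scaling factors from the trimmed mean of M values (TMM) ran from 0.912 to 1.094, the mitochondrial share from 1.87 to 4.98% and the share of the 10 most abundant genes from 3.56 to 7.1%. Over the 72 pairs of libraries within a group, a chi-square statistic of the counts ran from 5.48 to 192.81 per gene, so every pair differed by more than sampling noise and all libraries were kept.

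Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, the filterByExpr filter on low counts and the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Stroke contrasts compared each later stage with sham within a regimen, in a fit of that regimen's 18 libraries. Regimen contrasts compared each fasting regimen with AL within a stage, in a fit of that stage's 12 libraries. Average contrasts over the 6 stages, and interactions that ask whether any of the 5 stroke responses differed between regimens, used the 36 libraries of 2 regimens. This gave 45 contrasts. Log2 fold changes are given with their standard errors, and levels as TMM-scaled CPM with the SD over 3 libraries unless another n is given.

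Gene lists were written before the data were examined, as were the contrasts, the tests and the rule for named genes. There are 20 pathway lists and 18 cell type lists with 452 genes, 13 of them in more than 1 list. The pathway lists cover immediate early genes, heat shock chaperones, integrated and ER stress, hypoxia, cytokines and chemokines, interferon-stimulated genes, endothelial adhesion and leukocyte entry, barrier and matrix remodelling, complement, the antioxidant response, apoptosis and p53 targets, cell proliferation, synapse and neurotransmitter receptors, neurotrophic factors, ketone and fatty acid oxidation, cholesterol synthesis, glucocorticoid-responsive genes, the circadian clock, autophagy and lysosome, and insulin and mTOR signalling. The cell type lists cover neurons, medium spiny neurons, astrocytes, reactive astrocytes, homeostatic microglia, activated myeloid cells, neutrophils, monocytes and border macrophages, T cells, B cells, oligodendrocytes, their precursors, endothelial cells, mural cells, meningeal fibroblasts, choroid plexus, ependymal cells and erythrocytes. For each list the number of called members over all genes, the number called when adjusted over the list alone, the median log2 fold change and the camera test of limma 3.58.1 are reported. Camera values are its adjusted p over the lists and contrasts of a family. Camera used a preset correlation of 0.01 between genes, and was repeated with an estimated correlation. With the preset, 542 of 1542 tests of a list in a contrast passed at an adjusted p under 0.05, and no call held with an estimated correlation, where the smallest adjusted p was 0.122.

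Named genes had an adjusted p under 0.05, an average log2 CPM of at least 1, a symbol other than a gene model name and, for stroke and stagewise regimen contrasts, no overlap between the CPM values of the groups compared. Of these, the 5 largest rises and 5 largest falls were named for AL stroke contrasts, 3 of each for regimen contrasts at a stage, 8 of each for averages and the 10 smallest p-values for interactions, together with up to 4 members of a list. For a gene with no read in any sham library, the fold is given as a lower bound against a floor of 3 counts per library, which covers counting error only.

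Markers of 5 brain regions were added after region-specific genes were seen among the leading genes of the sham libraries. These 38 genes mark thalamus, hypothalamus, hippocampus, cortex and striatum, the striatum list is the medium spiny neuron list, and genes seen in that first look were left out.

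Similarity of stroke responses between regimens was given as Pearson's r of log2 fold changes across genes, which are not independent replicates, with a jackknife error over libraries. The regimens compared have separate sham libraries. The whole procedure was tested on simulated counts drawn from the real means and library sizes. In the simulated contrast of 24 h with sham in AL over 16274 genes, 7.6% of genes changed 1.5-fold, 50.7% of those changed 2-fold and 75% of those changed 4-fold were called, with 4 false calls by edgeR and 20 by DESeq2. For IF12 against AL at 3 h over 15708 genes these shares were 13.4, 53.8 and 89.4%, with 4 and 25 false calls. For the average of IF16 against AL over 16634 genes they were 72.3, 86.6 and 98.4%, with 6 and 14, and for the IF16 interaction over 16663 genes 1.5, 26.9 and 74.2%, with 0 and 30. Other splits of the real libraries called up to 5344 genes, so these false calls give no error rate for the real data.

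Alternatives chosen in advance were DESeq2 1.42.0 size factors in the edgeR fit, no filter on low counts, the DESeq2 test, a single fit of all 72 libraries, the replicate number as a block and leaving out each library in turn. Chosen after seeing the data were an offset that removes each library's trend on gene length, covariates for section position made from the thalamus and hypothalamus markers, a fit of only the groups compared, and the library left out of response correlations. Other splits of the same libraries were tested, 10 for 3 against 3 libraries and 100 drawn splits for 36 libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.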

Results

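Intermittent fasting and experimental stroke were combined in 1 design, with 4 feeding regimens crossed with 6 stages of stroke in mouse brain. The regimens were ad libitum feeding (AL), every-other-day fasting (EOD) and 12 or 16 h of daily fasting (IF12, IF16). The stages were sham, 1 h of ischemia without reperfusion (ischemia alone), and 3, 12, 24 and 72 h of reperfusion. Each of the 24 groups held 3 libraries. The first principal component of the 72 libraries took 29.5% of the variance, the second 9.6% and the third 9.3%. The comparisons asked how stroke changed expression over time in AL mice, and whether the same held in each fasting regimen. They also asked how fasting changed expression at each stage and on average, and whether the stroke response differed between fasted and AL mice.

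After ischemia alone, no gene in AL mice passed the edgeR test among 16452 genes, while 550 had an unadjusted p under 0.05 and DESeq2 called 14. Immediate early genes, which neurons induce within minutes of strong activity, had a median log2 fold change of 0.38, with 0 of 24 members called over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.471 with an estimated correlation). Markers of medium spiny neurons, the principal cells of the striatum, had a median of -1.71, with 0 of 9 called over all genes and 8 adjusted over the list alone (camera adjusted p = 1.97e-15; adjusted p = 0.301 with an estimated correlation). Hippocampus markers had a median of 2.46 in the same contrast. The remaining 36 lists had 0 called members.

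At 3 h of reperfusion, 4 genes rose and 1 fell in AL mice. Fosb, a partner of Jun in AP-1 complexes, rose from 17.8 ± 5.03 CPM in sham to 305 ± 77 CPM (log2 fold change 4.10 ± 0.45, adjusted p = 0.00144, edgeR). Maff, a small Maf transcription factor, rose from 2.72 ± 0.547 to 35.9 ± 15.5 CPM (3.72 ± 0.61, adjusted p = 0.049). Fosl2, also an AP-1 subunit, rose from 38.6 ± 12.2 to 211 ± 110 CPM (2.46 ± 0.37, adjusted p = 0.031). Irs2, an adaptor of insulin receptor signalling, rose by 1.62 ± 0.26 (adjusted p = 0.0374). Hes5, a Notch target of neural progenitors, fell from 6.65 ± 1.16 to 1.49 ± 0.481 CPM (-2.15 ± 0.33, adjusted p = 0.031). These were the 5 genes called by edgeR, against 123 by DESeq2, 51 with all 72 libraries in 1 fit and 30 with only the groups compared. Fosb (ENSMUSG00000003545) lies on chromosome 7, 19302696 to 19310051, minus strand. Without 1 library the count lay between 1, without sham replicate 1, sham replicate 2 or 3 h replicate 2, and 22, without 3 h replicate 1, and it was 2 without 3 h replicate 3. Fosb kept its call without any of the 6 libraries.

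In the lists at 3 h in AL few members were called over all genes. Of 24 immediate early genes, 3 were higher over all genes and 21 adjusted over the list alone, with a median of 1.71 (camera adjusted p = 4.61e-26; adjusted p = 0.122 with an estimated correlation). Cytokines and chemokines had a median of 3.54, or 3.09 with the member that had no sham read at its lower bound, with 0 of 20 called over all genes and 9 adjusted over the list alone (camera adjusted p = 1.46e-08; adjusted p = 0.471 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.69, with 0 of 12 called and 6 adjusted over the list alone (camera 1.19e-06; adjusted p = 0.455 with an estimated correlation). Circadian clock genes had a median of 0.55, with 0 of 17 called and 6 adjusted over the list alone (camera 2.73e-06; adjusted p = 0.301 with an estimated correlation). Irs2 was the called member among 15 genes of insulin and mTOR signalling, whose median was 0.24 (camera 0.00726; adjusted p = 0.471 with an estimated correlation).

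At 12 h, Ccl2 led the rises in AL mice among genes that met the rule for naming. Ccl2, which attracts monocytes, went from 0.0654 ± 0.0568 to 8.21 ± 9.2 CPM (6.83 ± 1.59, adjusted p = 0.0446, edgeR), and Msr1, a scavenger receptor of macrophages, rose by 6.13 ± 1.36 (adjusted p = 0.0373). The inducible chaperones Hspa1b (6.06 ± 1.26, adjusted p = 0.0292) and Hspa1a (5.40 ± 1.19, adjusted p = 0.0362) share nearly all of their sequence, so their separate values are uncertain. Ptx3, a secreted pattern recognition protein, rose from 0.287 ± 0.113 to 12.5 ± 10.8 CPM (5.43 ± 0.98, adjusted p = 0.0202). By the same rule the largest falls were in Rxrg, a retinoid receptor (-2.60 ± 0.56, adjusted p = 0.0323), and Gpr6, a receptor of striatal neurons (-2.29 ± 0.55, adjusted p = 0.0488). Itm2a (-1.82 ± 0.25, adjusted p = 0.00877), Slc47a1 (-1.81 ± 0.40, adjusted p = 0.0358) and Dach1 (-1.56 ± 0.32, adjusted p = 0.0244) fell too. In all, 251 genes changed, 175 higher and 76 lower, of which 150 and 44 changed at least 2-fold, and all 251 were among the 843 called by DESeq2. Each of the 6 libraries moved this count by over 1.5 times: it was 1, 20 and 3 without sham replicates 1, 2 and 3, and 44, 1347 and 3 without 12 h replicates 1, 2 and 3. It was 623 with all 72 libraries in 1 fit and 39 with only the groups compared. Of the 10 genes, Itm2a was the exception that lost its call without 1 library alone, sham replicate 1, and the others lost it without at least 4.

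**Figure D1:**
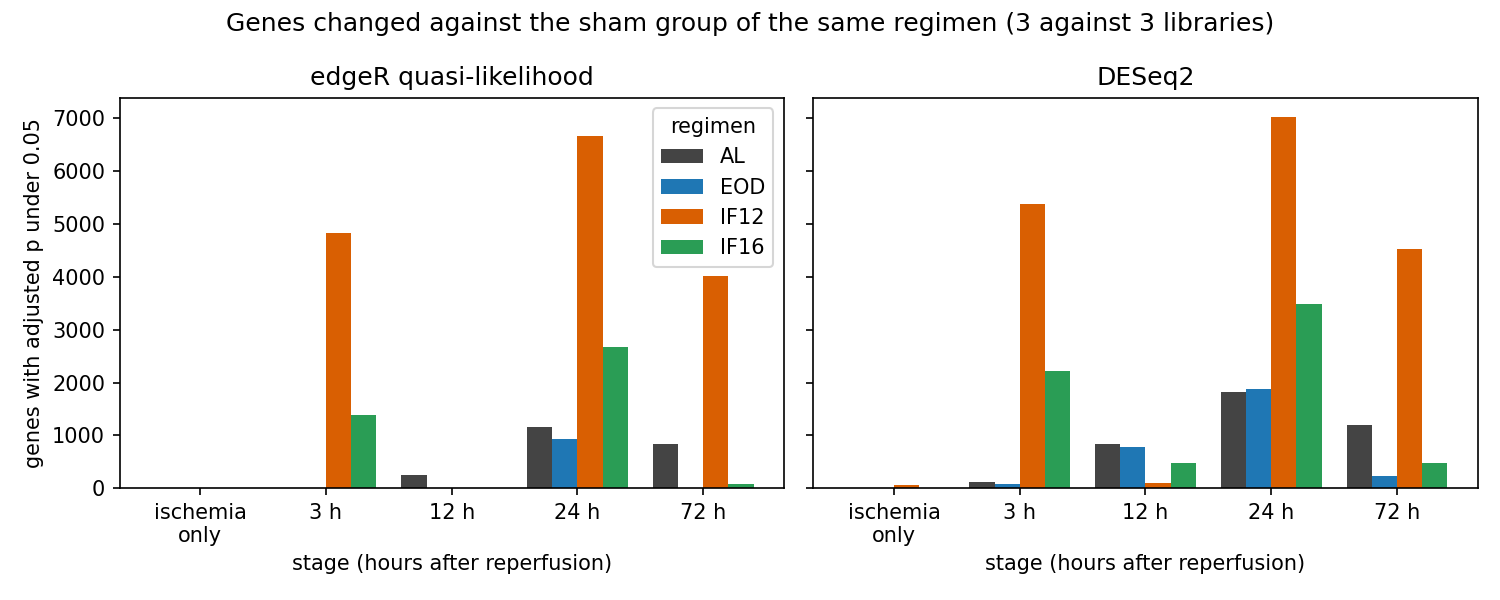
Number of genes changed against sham (y axis) at each stage (x axis) in each feeding regimen at an adjusted p under 0.05, by edgeR (left) and DESeq2 (right), with 3 libraries per group. By edgeR AL reached 1152 genes at 24 h, and IF12 had the tallest bars at 3, 24 and 72 h, with 6677 genes at 24 h.

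By list, 10 of 14 reactive astrocyte genes were higher at 12 h in AL and 13 adjusted over the list alone, with a median of 3.13 (camera adjusted p = 2.91e-14; adjusted p = 0.371 with an estimated correlation). Called members included Ptx3 and Timp1 (4.82 ± 0.85), an inhibitor of matrix metalloproteinases. Of 14 antioxidant genes 6 were higher and 8 adjusted over the list alone, median 0.60 (camera 1.97e-05; adjusted p = 0.36 with an estimated correlation). Called members included heme oxygenase Hmox1 (4.27 ± 1.00) and the metallothioneins Mt2 (2.21 ± 0.39) and Mt1 (1.60 ± 0.25). Of 12 glucocorticoid-responsive genes 5 were higher and 11 adjusted over the list alone, median 1.16 (camera 2.56e-10; adjusted p = 0.301 with an estimated correlation). Called members included Cdkn1a, a cell cycle inhibitor (3.04 ± 0.45), and Fkbp5, a co-chaperone of the glucocorticoid receptor (1.78 ± 0.31). Immediate early genes had 5 of 24 higher and 8 adjusted over the list alone, median 0.78 (camera 3.73e-05; adjusted p = 0.465 with an estimated correlation). Heat shock chaperones had 3 of 15 higher and 6 adjusted over the list alone, median 0.99 (camera 1.41e-05; adjusted p = 0.548 with an estimated correlation). Integrated and ER stress genes had 2 of 16 higher and 11 adjusted over the list alone, median 0.64 (camera 1.19e-06; adjusted p = 0.465 with an estimated correlation). The stress transcription factor Atf3 had a log2 fold change of 5.05 ± 0.93. Barrier and matrix remodelling genes had 3 of 16 higher and 11 adjusted over the list alone, median 1.54 (camera 7.27e-07; adjusted p = 0.455 with an estimated correlation). Hypoxia genes had 0 of 14 called and 6 adjusted over the list alone, median 0.52 (camera 0.00777; adjusted p = 0.52 with an estimated correlation). Of 9 genes of monocytes and border macrophages, 3 were higher and 6 adjusted over the list alone, median 2.25 (camera 1.31e-05; adjusted p = 0.432 with an estimated correlation). Medium spiny neuron genes had 1 of 9 lower and 8 adjusted over the list alone, median -1.71 (camera 2.22e-07; adjusted p = 0.455 with an estimated correlation), with hippocampus markers at a median of 1.85.

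At 24 h, among genes that met the rule for naming, Il1rn had the largest rise in AL mice and Drd2 the largest fall. Il1rn, the interleukin 1 receptor antagonist, had no read in any sham library and stood at 11.7 ± 11.2 CPM, at least 79.6-fold higher (adjusted p = 0.0166, edgeR). Msr1 rose to 16.8 ± 4.04 CPM (7.84 ± 1.34, adjusted p = 0.00549) and Ccl2 to 14.9 ± 12.1 CPM (7.67 ± 1.59, adjusted p = 0.0118). Tgm1, a protein cross-linking enzyme, rose from 0.25 ± 0.101 to 50.1 ± 24.9 CPM (7.61 ± 1.16, adjusted p = 0.00342) and Klk9, a serine protease, to 10.4 ± 7.18 CPM (7.53 ± 0.98, adjusted p = 0.0011). Drd2, the D2 dopamine receptor, fell from 64.6 ± 29 to 5.23 ± 3.7 CPM (-3.64 ± 0.78, adjusted p = 0.0134). Adora2a, an adenosine receptor carried by the same neurons, fell from 158 ± 78 to 15.3 ± 9.61 CPM (-3.38 ± 0.73, adjusted p = 0.0144). Gpr6 (-3.58 ± 0.59, adjusted p = 0.00437), Sh3rf2 (-3.36 ± 0.72, adjusted p = 0.0132) and Serpina9 (-3.30 ± 0.69, adjusted p = 0.012) fell with them. Drd2 (ENSMUSG00000032259) lies on chromosome 9, 49340627 to 49408177, plus strand, and Ccl2 (ENSMUSG00000035385) on chromosome 11, 82035571 to 82037453, plus strand. Of 1152 genes that changed, 661 were higher and 491 lower, 516 and 228 of them at least 2-fold, and DESeq2 shared 1147 of them among its 1817. The count was 457, 426 and 267 without sham replicates 1, 2 and 3, and 420 and 443 without 24 h replicates 2 and 3, while it was 1293 without 24 h replicate 1. Adora2a, Sh3rf2, Serpina9, Ccl2 and Il1rn lost their calls without at least 1 library, and the other 5 did not.

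Cytokines and chemokines had 14 of 20 members higher at 24 h in AL and 20 adjusted over the list alone, with a median of 5.26. The median stayed at 5.26 with the member that had no sham read at its lower bound (camera adjusted p = 2.95e-14; adjusted p = 0.455 with an estimated correlation). Of 14 reactive astrocyte genes 13 were higher and 14 adjusted over the list alone, median 3.43 (camera 2.83e-17; adjusted p = 0.301 with an estimated correlation). Serpina3n, a secreted protease inhibitor, had a log2 fold change of 4.63 ± 0.53. Gfap, the intermediate filament of astrocytes, rose by 2.91 ± 0.26 (adjusted p = 3.4e-05) and was the called member among 9 general astrocyte genes. Activated myeloid genes had 9 of 11 higher and 11 adjusted over the list alone, median 2.89 (camera 8.96e-08; adjusted p = 0.388 with an estimated correlation). The lectin Lgals3 had a log2 fold change of 4.60 ± 1.00 and Spp1, which encodes osteopontin, one of 4.59 ± 0.91. Interferon-stimulated genes had 13 of 20 higher and 17 adjusted over the list alone, median 1.36 (camera 6.21e-12; adjusted p = 0.371 with an estimated correlation). Neutrophil genes had 4 of 6 higher and 5 adjusted over the list alone, median 4.72 (camera 0.00455; adjusted p = 0.523 with an estimated correlation). Complement genes had 5 of 12 higher and 6 adjusted over the list alone, median 1.16 (camera 1.31e-05; adjusted p = 0.455 with an estimated correlation). Medium spiny neuron genes had 8 of 9 lower and 8 adjusted over the list alone, median -2.50 (camera 7.98e-09; adjusted p = 0.455 with an estimated correlation), beside a median of 0.89 for hippocampus markers. Synapse and receptor genes had 5 of 18 lower and 9 adjusted over the list alone, median -0.46 (camera 6.71e-06; adjusted p = 0.371 with an estimated correlation). General neuron genes had 0 of 12 called and 0 adjusted over the list alone, median -0.32 (camera 0.0157; adjusted p = 0.55 with an estimated correlation).

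Further lists had called members at 24 h in AL. Antioxidant genes had 7 of 14 higher and 9 adjusted over the list alone, median 0.81 (camera adjusted p = 2.1e-08; adjusted p = 0.241 with an estimated correlation). Apoptosis and p53 targets had 5 of 14 higher and 8 adjusted over the list alone, median 0.59 (camera 3.47e-05; adjusted p = 0.455 with an estimated correlation). Barrier and matrix remodelling genes had 7 of 16 higher and 10 adjusted over the list alone, median 1.64 (camera 2.52e-06; adjusted p = 0.465 with an estimated correlation). The metalloproteinase Mmp3 had a log2 fold change of 8.20 ± 1.94. Endothelial adhesion and leukocyte entry genes had 3 of 10 higher and 1 lower, and 6 adjusted over the list alone, median 1.45 (camera 0.00983; adjusted p = 0.558 with an estimated correlation). Hypoxia genes had 2 of 14 higher and 4 adjusted over the list alone, median 0.34 (camera 0.0235; adjusted p = 0.558 with an estimated correlation), namely Adm, a vasodilator peptide, and the glycolytic enzyme Hk2. Neurotrophic factors had 2 of 9 higher and 2 adjusted over the list alone, with Gdf15, a stress-induced cytokine, at 5.34 ± 1.07. Ketone and fatty acid oxidation genes had 2 of 16 higher and 6 adjusted over the list alone, while their median was -0.04 and the camera test pointed up (camera 0.903; adjusted p = 0.982 with an estimated correlation). Of the endothelial cell genes Pecam1 was higher, with 1 of 9 called over all genes and 1 adjusted over the list alone. Among mural cell genes the pericyte marker Rgs5 fell by 0.68 ± 0.18, with 1 of 8 called over all genes and 2 adjusted over the list alone.

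At 72 h, among genes that met the rule for naming, Cd5l had the largest rise in AL mice and Drd2 the largest fall. Cd5l, a secreted macrophage protein, had no read in any sham library and stood at 11.8 ± 12.3 CPM, at least 80.2-fold higher (adjusted p = 0.00733, edgeR). Tgm1 rose by 7.99 ± 1.17 (adjusted p = 0.0011) and Msr1 by 7.24 ± 1.34 (adjusted p = 0.00413). Siglec1, a sialic acid receptor of macrophages, rose from 0.134 ± 0.0283 to 10.4 ± 9.06 CPM (6.21 ± 0.64, adjusted p = 4.38e-05). Spp1 rose from 7.32 ± 2.45 to 339 ± 449 CPM (5.52 ± 0.95, adjusted p = 0.00259), an SD larger than the mean. The striatal genes Drd2 (-2.86 ± 0.74, adjusted p = 0.0332), Syndig1l (-2.79 ± 0.63, adjusted p = 0.0148), Rgs9 (-2.78 ± 0.64, adjusted p = 0.0173) and Gpr6 (-2.75 ± 0.56, adjusted p = 0.00751) fell. So did Cd4 (-2.80 ± 0.78, adjusted p = 0.0484), known from helper T cells. Its means in AL went up and down with those of Drd2, at 18.3, 5.11, 18.2 and 2.22 CPM in sham, after ischemia alone and at 3 and 24 h against 64.6, 15.2, 52.1 and 5.23 CPM. Spp1 (ENSMUSG00000029304) lies on chromosome 5, 104435118 to 104441050, plus strand. Of 844 genes that changed, 736 were higher and 108 lower, 633 and 58 of them at least 2-fold, and DESeq2 shared 839 of them among its 1190. The count was 471, 457 and 448 without sham replicates 1, 2 and 3, 334 without 72 h replicate 3 and 312 with only the groups compared. Drd2, Cd4, Syndig1l and Rgs9 each lost their calls without at least 4 of the 6 libraries, and the other 6 kept theirs without any 1 library.

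**Figure D2:**
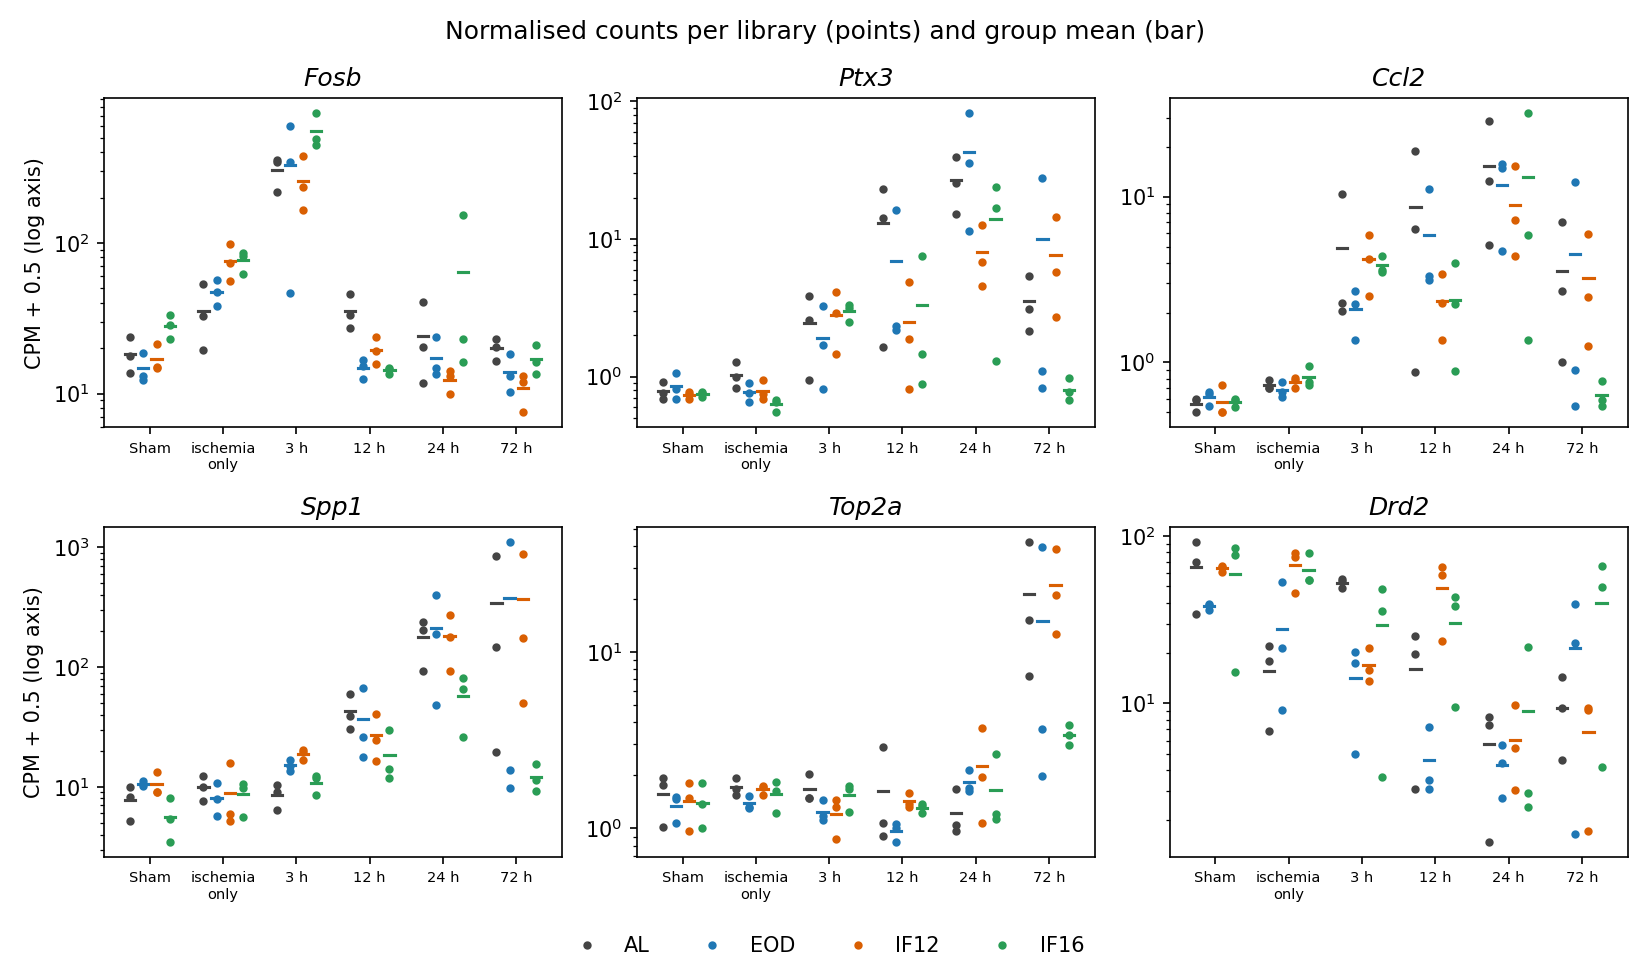
Levels in CPM (0.5 added, log axis) of Fosb, Ptx3, Ccl2, Spp1, Top2a and Drd2 in each of the 72 libraries, by stage and feeding regimen. Each point is a library and each bar the mean of a group of 3 libraries. Spp1 at 72 h stood at 11.5 CPM in IF16 against 339 in AL.

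Interferon-stimulated genes had 17 of 20 members higher at 72 h in AL and 19 adjusted over the list alone, with a median of 2.37 (camera adjusted p = 2.86e-29; adjusted p = 0.122 with an estimated correlation). Called members included the nucleic acid sensor Zbp1 (4.24 ± 0.53) and Oas1a (3.63 ± 0.35). Proliferation genes had 14 of 15 higher and 15 adjusted over the list alone, median 3.04 (camera 3.04e-19; adjusted p = 0.301 with an estimated correlation). Topoisomerase Top2a went from 1.08 ± 0.484 to 20.9 ± 18.2 CPM (4.26 ± 0.67, adjusted p = 0.00138, edgeR). At 24 h the same list had 0 of 15 called and a median of -0.39. Activated myeloid genes had 9 of 11 higher and 9 adjusted over the list alone, median 4.27 (camera 4.74e-12; adjusted p = 0.301 with an estimated correlation). Lgals3 had a log2 fold change of 5.45 ± 1.02 and the cystatin Cst7 one of 4.65 ± 0.65. Complement genes had 8 of 12 higher and 11 adjusted over the list alone, median 2.02 (camera 3.9e-12; adjusted p = 0.278 with an estimated correlation). Homeostatic microglia genes had 3 of 9 higher and 7 adjusted over the list alone, median 1.09 (camera 1.09e-06; adjusted p = 0.455 with an estimated correlation), after a median of -0.61 at 12 h. Monocyte and border macrophage genes had 5 of 9 higher and 8 adjusted over the list alone, median 2.98 (camera 5.11e-08; adjusted p = 0.301 with an estimated correlation). Meningeal fibroblast genes had 5 of 7 higher and 7 adjusted over the list alone, median 2.56 (camera 2.99e-07; adjusted p = 0.371 with an estimated correlation). The collagen Col3a1 had a log2 fold change of 4.09 ± 0.72. Reactive astrocyte genes had 7 of 14 higher and 11 adjusted over the list alone, median 2.58 (camera 4.74e-12; adjusted p = 0.432 with an estimated correlation). Vim had a log2 fold change of 3.78 ± 0.45 and Gfap one of 3.67 ± 0.26.

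Medium spiny neuron genes were still lower at 72 h in AL, 8 of 9 over all genes and 9 adjusted over the list alone, with a median of -2.07 (camera adjusted p = 5.13e-09; adjusted p = 0.452 with an estimated correlation). Hippocampus markers had a median of 1.91. Synapse and receptor genes had 4 of 18 lower and 6 adjusted over the list alone, median -0.29 (camera 0.000788; adjusted p = 0.455 with an estimated correlation). Autophagy and lysosome genes had 5 of 15 higher and 6 adjusted over the list alone, median 0.23 (camera 0.00334; adjusted p = 0.465 with an estimated correlation). Erythrocyte genes had 1 of 5 lower and 5 adjusted over the list alone, median -1.40 (camera 1.84e-05; adjusted p = 0.455 with an estimated correlation). Called members included the hemoglobin gene Hbb-bt (-1.57 ± 0.35), whose reads may be shared with Hbb-bs. Oligodendrocyte genes had 1 of 9 higher, the myelin tight junction gene Cldn11 (1.08 ± 0.26). T cell genes had 1 of 3 lower, which was Cd4, the gene that went with Drd2, and B cell genes had 0 of 3 called with a median of -0.57.

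**Figure D3:**
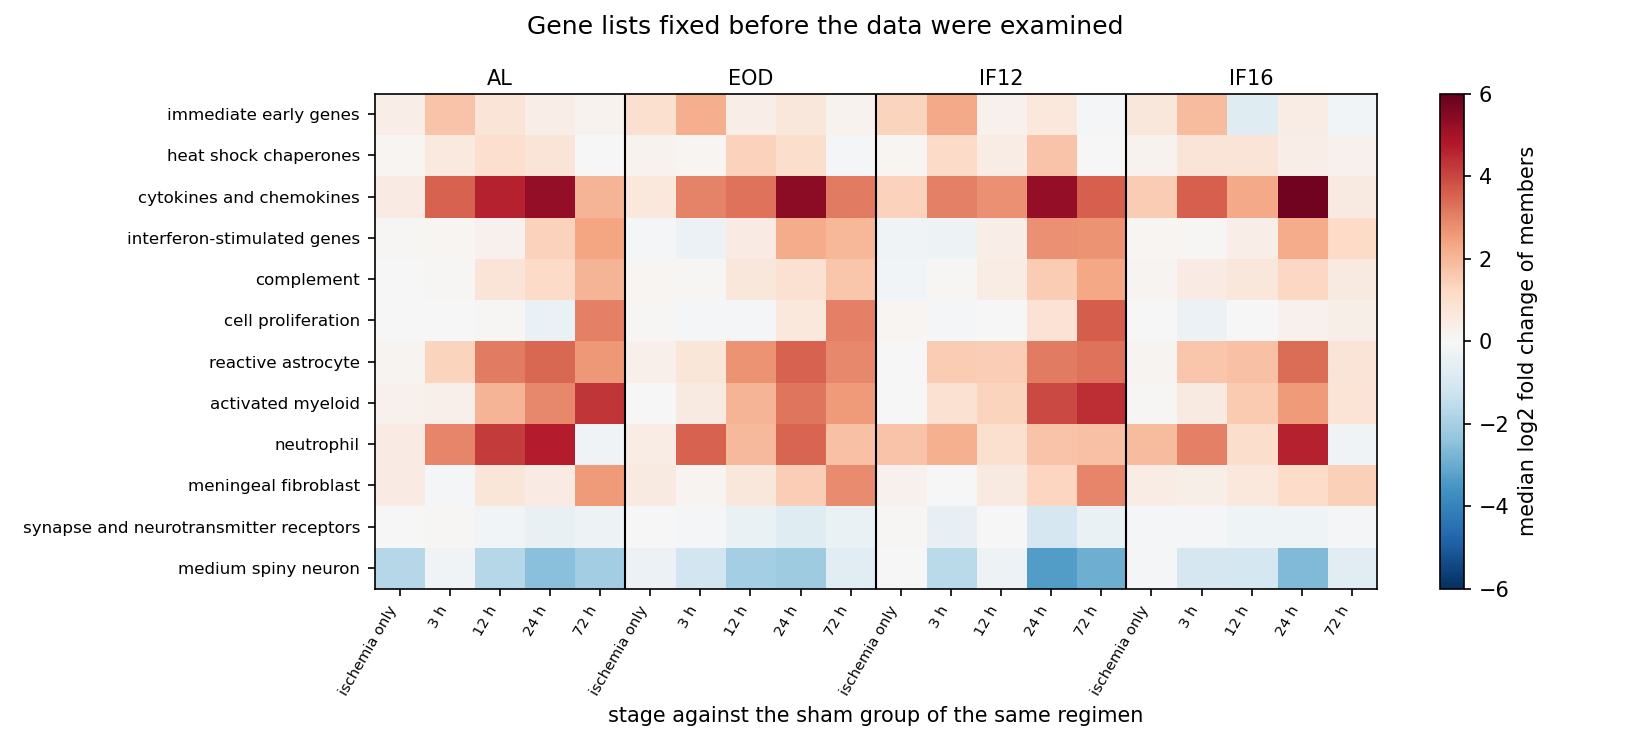
Median log2 fold change against sham of the members of 12 of the 38 gene lists (y axis) at each stage and feeding regimen (x axis), on a colour scale from -6 to 6. In AL, cytokines and chemokines had a median of 5.26 at 24 h and proliferation genes one of 3.04 at 72 h.

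In EOD mice at 24 h, 933 of 16415 genes changed, 360 higher and 573 lower, against 1875 by DESeq2. Cytokines and chemokines had 13 of 20 members higher and 20 adjusted over the list alone, with a median of 5.37, or 5.20 with the member without sham reads at its lower bound (camera adjusted p = 1.59e-14; adjusted p = 0.455 with an estimated correlation). Medium spiny neuron genes had 5 of 9 lower and 7 adjusted over the list alone, with a median of -2.12 and hippocampus markers at 0.17. Of 17 circadian clock genes 4 were lower and 5 adjusted over the list alone, among them Hlf (-1.21 ± 0.21) and Dbp (-0.97 ± 0.19), transcription factors driven by the clock. The list median was -0.16 (camera 0.028, 0.52 with an estimated correlation). At 3 h 9 genes changed, 5 higher and 4 lower. Immediate early genes had 1 of 24 higher and 19 adjusted over the list alone, median 2.16 (camera 3.83e-21, 0.301 with an estimated correlation). Ischemia alone gave 0 genes by edgeR, 368 at an unadjusted p under 0.05 and 4 by DESeq2. At 12 h 6 genes changed, 1 higher and 5 lower, with 778 by DESeq2, and 72 h gave 0 genes, 1878 at an unadjusted p under 0.05 and 237 by DESeq2. All 72 libraries in 1 fit gave 58, 989, 2632 and 853 genes at 3, 12, 24 and 72 h, and only the groups compared 40, 561, 3427 and 0. At 72 h replicate 2 stood apart, at 105.7 on the first principal component against -10 and -17.5 for the other 2. The 24 h count was 36 without sham replicate 3, 52 without 24 h replicate 3, 88 without sham replicate 2, 197 without 24 h replicate 1 and 293 without sham replicate 1. The 72 h count was 631 without 72 h replicate 3. The 12 h count was 552 without 12 h replicate 1 and at most 3 without any other, and the 3 h count 33 without 3 h replicate 1 and at most 3 without any other.

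IF12 mice had the most called genes at 3, 24 and 72 h, a difference that was not tested. At these stages the slope on log2 gene length of log2 CPM, centred per gene, also lay apart from IF12 sham (-0.012 to 0.109), at -0.12 to -0.094, -0.149 to -0.112 and -0.077 to -0.037, but not at 12 h (0.087 to 0.108). With the length offset the counts at 3, 24 and 72 h were 4325, 6333 and 3940. At 3 h, 4835 of 16426 genes changed, 2206 higher and 2629 lower. Immediate early genes had 22 of 24 members higher and 23 adjusted over the list alone, median 2.28 (camera 5.28e-17, 0.301 with an estimated correlation). Fos stood at 4.39 ± 0.43 and Fosb at 3.97 ± 0.32. Integrated and ER stress genes had 11 of 16 higher and 12 adjusted over the list alone, median 1.27 (camera 2.54e-08; 0.455 with an estimated correlation). Cholesterol synthesis genes had 13 of 16 higher and 14 adjusted over the list alone, median 0.82 (camera 3.05e-10; 0.432 with an estimated correlation). Called members included the mevalonate pathway enzymes Mvd (1.53 ± 0.14) and Idi1 (1.20 ± 0.15). Medium spiny neuron genes had 8 of 9 lower and 8 adjusted over the list alone, median -1.64 (camera 0.00107, 0.567 with an estimated correlation). Hippocampus markers stood at 0.47. At 24 h, 6677 genes changed, 3327 higher and 3350 lower, 1177 and 836 of them at least 2-fold. Of synapse and receptor genes 17 of 18 were lower, with 17 adjusted over the list alone and a median of -1.02 (camera 2.1e-08; 0.455 with an estimated correlation). At 72 h, 4019 changed, 2251 higher and 1768 lower. All 15 proliferation genes were higher, with 15 adjusted over the list alone and a median of 3.65 (camera 1.08e-15; 0.301 with an estimated correlation). Ischemia alone changed 8 genes, 7 higher and 1 lower, and 12 h changed 2, both lower, with 57 and 100 by DESeq2, and without ischemia alone replicate 2 the 8 became 38. Without 1 library the 3 h count went down to 2473 (sham replicate 2), with 2577 and 3022 without 3 h replicates 3 and 2 and 2809 without sham replicate 3. The 24 h count went down to 4418 (24 h replicate 1) and the 72 h count to 1746 (72 h replicate 2), with 2009 and 2170 without sham replicates 2 and 3 and 1209 with only the groups compared.

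In IF16 mice, 1391 of 16355 genes changed at 3 h, 729 higher and 662 lower, and 2670 at 24 h, 1382 higher and 1288 lower, whereas 83 changed at 72 h, 31 higher and 52 lower. At 3 h, 22 of 24 immediate early genes were higher and 23 adjusted over the list alone, median 1.90. Camera gave 5.29e-21, and 0.214 with an estimated correlation. Bdnf, a neurotrophin released with activity, rose by 2.28 ± 0.25 (adjusted p = 0.000317, edgeR). Cholesterol synthesis genes had 10 of 16 higher and 13 adjusted over the list alone, median 0.92 (camera 6.65e-10, 0.455 with an estimated correlation). At 24 h, all 18 tested cytokines and chemokines were higher, with 18 adjusted over the list alone and a median of 5.77 (camera 7.19e-09; adjusted p = 0.465 with an estimated correlation). All 14 reactive astrocyte genes were higher too and 14 adjusted over the list alone, median 3.36 (camera 4.08e-12, 0.323 with an estimated correlation). At 72 h, meningeal fibroblast genes had 4 of 7 higher and 6 adjusted over the list alone, median 1.44 (camera 2.56e-10; adjusted p = 0.122 with an estimated correlation). Proliferation genes had 0 of 12 called and 1 adjusted over the list alone, median 0.35 (camera 0.00214, 0.465 with an estimated correlation). Activated myeloid genes had 0 of 11 called and 0 adjusted over the list alone, median 0.81 (camera 0.0114, 0.607 with an estimated correlation). Ischemia alone changed 2 genes and 12 h 14, with 6 and 472 by DESeq2, and without 12 h replicate 1 the 14 became 224. The 72 h count was at most 7 without any 1 of the 6 libraries. With only the groups compared, IF16 had 73 genes at 24 h and 578 at 72 h, against 1261 and 312 in AL. The 3 h count was 158 without sham replicate 3, 300 without sham replicate 2, 333 and 520 without 3 h replicates 1 and 3 and 842 without sham replicate 1. The 24 h count was 564 and 1103 without sham replicates 3 and 2 and 1591 without 24 h replicate 2.

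Across genes, the log2 fold changes of the fasted mice were set against those of AL mice at each stage. Pearson's r at 24 h was 0.777 ± 0.072 (jackknife error) for EOD, 0.767 ± 0.078 for IF12 and 0.791 ± 0.173 for IF16. At 72 h it was 0.749 ± 0.422 for EOD, 0.807 ± 0.127 for IF12 and 0.362 ± 0.191 for IF16, and the slope on the AL response was 0.765, 1.006 and 0.232. At 12 h r was 0.763 ± 0.148, 0.641 ± 0.141 and 0.455 ± 0.187 for EOD, IF12 and IF16. At 3 h r was 0.462 ± 0.115, 0.302 ± 0.287 and 0.409 ± 0.228, and after ischemia alone 0.138 ± 0.337, 0.199 ± 0.199 and 0.082 ± 0.268. Genes are not independent replicates, and the 15 values were not tested against each other. Without 1 library r was as low as 0.294 for EOD at 72 h, 0.116 for IF12 and 0.239 for IF16 at 3 h and, after ischemia alone, -0.021 for EOD, 0.029 for IF12 and -0.079 for IF16.

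Between fasted and AL mice at the same stage, genes differed by edgeR in 2 of 18 comparisons, both at 3 h of reperfusion. In EOD mice at 3 h, Prkcd, a protein kinase C gene strongly expressed in thalamus, stood at 273 ± 76.2 CPM against 20.4 ± 7.21 in AL (3.76 ± 0.62, adjusted p = 0.0419, edgeR). Wnt9b (3.64 ± 0.48, adjusted p = 0.0162) and Rab37 (3.26 ± 0.56, adjusted p = 0.0419) were higher too. Mme (-1.87 ± 0.34, adjusted p = 0.0419), the serotonin receptor Htr1b (-1.74 ± 0.29, adjusted p = 0.0419) and the retinoic acid receptor Rarb (-1.72 ± 0.32, adjusted p = 0.0461) were lower. In this contrast thalamus markers had a median of 1.33, hippocampus markers 1.75, cortex markers -0.26 and striatum markers -1.67. In all, 42 genes differed, 34 higher and 8 lower, and all 42 were among the 379 of DESeq2. The count was 0 without any of the AL libraries or EOD replicate 2, 9 without EOD replicate 3 and 456 without EOD replicate 1. It was 0 with covariates for section position or with all 72 libraries in 1 fit. Prkcd (ENSMUSG00000021948) lies on chromosome 14, 30595354 to 30626210, minus strand.

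In IF12 mice at 3 h, 1448 genes differed from AL, 486 higher and 962 lower, with 1400 of them among the 2673 of DESeq2. The hypothalamic neuropeptide gene Pmch (4.91 ± 1.32, adjusted p = 0.046, edgeR), the VIP receptor Vipr2 (3.15 ± 0.73, adjusted p = 0.0328) and the troponin Tnnt1 (2.92 ± 0.69, adjusted p = 0.0356) were higher. Oxytocin (Oxt) was lower (-3.61 ± 0.92, adjusted p = 0.0404). Also lower were Pde10a, a phosphodiesterase of striatal neurons, at 49 ± 8.11 against 316 ± 52.4 CPM (-2.69 ± 0.55, adjusted p = 0.0308) and Gprin3 (-2.32 ± 0.41, adjusted p = 0.0297). The astrocyte genes Gfap (1.41 ± 0.34) and S100b (1.17 ± 0.20) were among 3 of 9 higher, with 4 adjusted over the list alone and a median of 0.45 (camera adjusted p = 0.0123; adjusted p = 0.886 with an estimated correlation). Synapse and receptor genes had 3 of 18 lower and 5 adjusted over the list alone, median -0.64 (camera 0.00348; adjusted p = 0.886 with an estimated correlation). Clock genes moved both ways, with Nr1d1 at 1.09 ± 0.24, Clock at -0.86 ± 0.22 and Per3 at -0.86 ± 0.24. Hippocampus markers had a median of 0.77, thalamus markers 0.42, hypothalamus markers -0.18, cortex markers -0.44 and striatum markers -1.32. The count was 0 without any 1 of 5 libraries and 1343 without AL replicate 2. It was 0 with covariates for section position, 3 with the replicate number as a block, 659 with a gene length offset and 3096 with only the groups compared. The mitochondrial share of counts was 3.75 to 4.98% in these IF12 libraries against 2.72 to 2.82% in AL, and that of the 10 most abundant genes 5.42 to 6.82% against 4.10 to 4.35%. Pde10a (ENSMUSG00000023868) lies on chromosome 17, 8525372 to 8986648, plus strand, and Pmch (ENSMUSG00000035383) on chromosome 10, 88091072 to 88092375, plus strand.

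**Figure D4:**
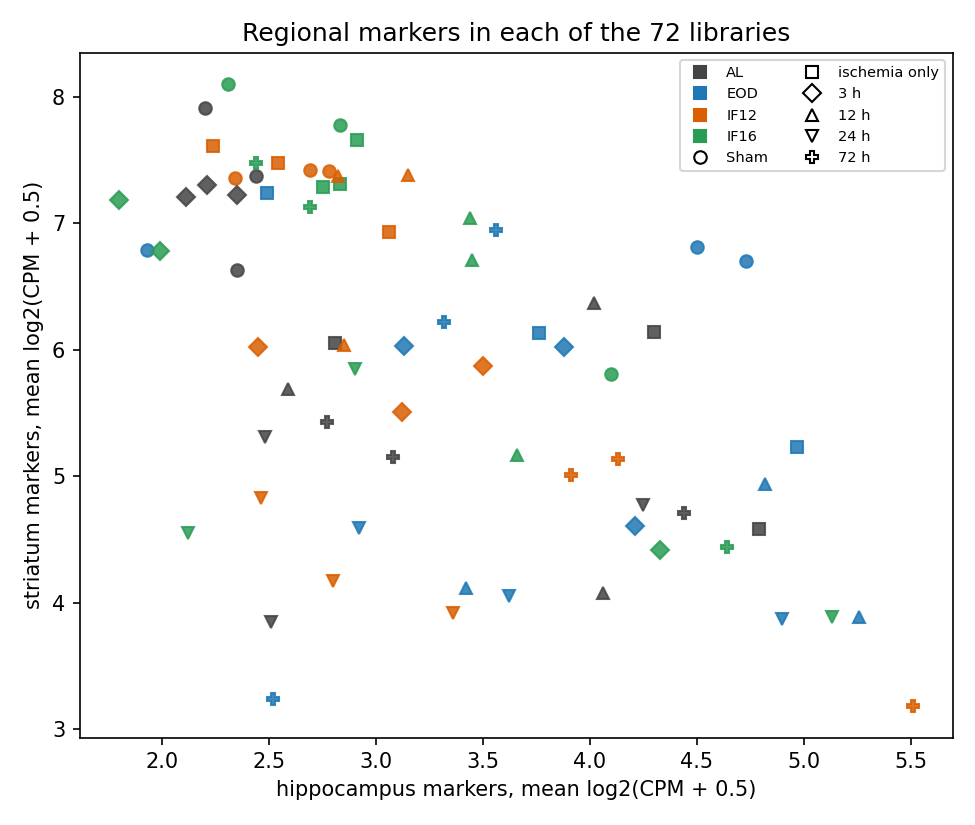
Mean log2(CPM + 0.5) of striatum markers against that of hippocampus markers in each of the 72 libraries, with colours for the feeding regimens and shapes for the stages. Libraries with higher hippocampus scores had lower striatum scores in several groups, for example EOD at 3 h, at means of 3.74 and 5.55 against 2.23 and 7.24 in AL.

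In sham mice, fasting gave 0 genes by edgeR in each regimen, with 952, 1823 and 5094 genes at an unadjusted p under 0.05 and 29, 22 and 2702 by DESeq2 for EOD, IF12 and IF16. The circadian clock list had 0 of 17 called over all genes in each regimen and 8, 7 and 12 adjusted over the list alone. In IF16 its median was 0.28 (camera 0.00135, 0.886 with an estimated correlation). Per2 stood at 1.20 ± 0.18 (adjusted p = 0.0628 over all genes, 0.000304 over the list alone) and Per3 at 1.05 ± 0.24. The myelin gene Mbp stood at -0.64 ± 0.19 in IF16 (adjusted p = 0.0717 over all genes, 0.0181 over the list alone). Of 9 oligodendrocyte genes 8 passed over the list alone and 0 over all. Length slopes ran from 0.102 to 0.116 in IF16 but -0.12 to 0.051 in AL, so length bias was not told apart from fasting. Without AL replicate 3 (slope 0.051) IF16 gave 4751 genes, with the replicate block 1261 and with no filter 92.

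The other 13 comparisons at a stage gave 0 genes by edgeR. After ischemia alone, EOD, IF12 and IF16 had 648, 1951 and 2854 genes at an unadjusted p under 0.05 and 1, 155 and 176 by DESeq2, and IF12 had 1257 genes without IF12 replicate 2. At 12 h these numbers were 544, 2149 and 1406, with 1, 164 and 86 by DESeq2. At 24 h they were 1164, 1924 and 423, with 3, 123 and 0, and at 72 h 449, 377 and 844, with 0 in each. IF16 at 3 h had 584 and 0. Other edgeR fits called genes, with only the groups compared 3042 for IF16 after ischemia alone and 152 for IF16 at 72 h, and with all 72 libraries 567 for IF16 at 72 h, 48 for IF12 at 24 h and 16 for IF12 at 12 h. Medium spiny neuron genes after ischemia alone had medians of 1.44 in IF12 and 1.58 in IF16, with 7 and 9 of 9 adjusted over the list alone and 0 over all genes. Hippocampus markers went the other way there, with medians of -1.56 and -1.52. Immediate early genes at 12 h in IF16 had a median of -1.37, with 18 of 24 adjusted over the list alone and 0 over all genes (camera adjusted p = 1.44e-13; adjusted p = 0.886 with an estimated correlation). Interferon-stimulated genes at 24 h in IF12 had a median of 1.21, with 15 of 20 adjusted over the list alone and 0 over all genes (camera 3.05e-09; adjusted p = 0.886 with an estimated correlation). Activated myeloid genes at 72 h in IF16 had a median of -3.07, with 9 of 11 adjusted over the list alone and 0 over all genes (camera 6.74e-08; adjusted p = 0.886 with an estimated correlation). Striatum markers had a median of 1.83 there.

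Averaged over the 6 stages, IF16 mice had lower levels of Spp1, Serpina3n, Vim and C1q genes than AL mice. Spp1 stood at 18.4 ± 21 CPM in IF16 against 97.2 ± 201 in AL (n = 18 libraries each; -1.35 ± 0.29, adjusted p = 0.0381, edgeR). Serpina3n stood at 46.6 ± 57.3 against 148 ± 174 CPM (-1.20 ± 0.20, adjusted p = 0.012). Lrg1 (-1.11 ± 0.25), Capg (-0.94 ± 0.20) and Cd52 (-0.87 ± 0.18) were also lower. So were S100a11 (-0.83 ± 0.17), S100a4 (-0.79 ± 0.19) and Vim (-0.78 ± 0.16). Adjusted p-values of these genes ran from 0.0338 to 0.05 (edgeR). The gap was not even over the stages. Vim stood at 38.5 CPM in IF16 against 41 in AL in sham, 76.9 against 57.3 at 3 h and 65.6 against 567 at 72 h. For Spp1 these means were 5.15 against 7.32, 10.4 against 8.1 and 11.5 against 339 CPM. The SDs over 18 libraries include such differences between stages. Abi3bp (0.89 ± 0.19), Hs6st3 (0.67 ± 0.16), Hmcn1 (0.64 ± 0.15), the Hedgehog receptor Ptch1 (0.52 ± 0.12), Mir124a-1hg (0.48 ± 0.11), Sgcz (0.47 ± 0.11), Zfp382 (0.47 ± 0.11) and Lgi2 (0.45 ± 0.11) were higher, with adjusted p-values from 0.0338 to 0.0492. Of 105 genes, 32 were higher and 73 lower, against 827 by DESeq2. Complement genes had 3 of 12 lower, the C1q chain genes C1qa, C1qb (-0.55 ± 0.12) and C1qc, and 6 adjusted over the list alone, median -0.38 (camera adjusted p = 0.000695; adjusted p = 0.534 with an estimated correlation). Reactive astrocyte genes had 2 of 14 lower and 10 adjusted over the list alone, median -0.72 (camera 1.17e-07; 0.534 with an estimated correlation). Activated myeloid genes had 1 of 11 lower and 8 adjusted over the list alone, median -0.74 (camera 2.14e-05; 0.534 with an estimated correlation). The clock repressor Nr1d2 was higher by 0.41 ± 0.07 (adjusted p = 0.012), and striatum markers had a median of 0.68. The count moved by over 1.5 times without 33 of the 36 libraries, from 2 without, among others, 3 h AL replicate 2 to 1445 without 12 h IF16 replicate 2. It was 1 with all 72 libraries in 1 fit and 1309 with covariates for section position. Serpina3n was the named gene that kept its call without any 1 library.

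EOD and IF12 did not give a called gene on average by edgeR, with 1006 and 1064 genes at an unadjusted p under 0.05 and 8 and 23 by DESeq2. In EOD the choroid plexus list, which produces cerebrospinal fluid, had 0 of 8 called over all genes and 8 adjusted over the list alone, with a median of 1.00 (camera adjusted p = 1.12e-08; adjusted p = 0.534 with an estimated correlation). Hippocampus markers were at 0.76 and striatum markers at -0.51. In IF12 the circadian clock list had 0 of 17 called and 8 adjusted over the list alone, with a median of 0.10 (camera 2.22e-05; adjusted p = 0.534 with an estimated correlation). Leaving out 1 library gave at most 5 genes in EOD, without sham EOD replicate 3, and at most 26 in IF12, without 24 h AL replicate 1.

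IF16 and IF12 differed in 2139 genes on average, 1196 higher and 943 lower in IF16, with 2844 by DESeq2. Spp1 (-1.51 ± 0.27), Lgals3 (-1.24 ± 0.32), the neuroendocrine factor Insm2 (-1.19 ± 0.26) and the oligodendrocyte protease Klk6 (-1.17 ± 0.25) were lower in IF16. So were Gtse1 (-1.13 ± 0.26), Bcl3 (-1.04 ± 0.28), Serpina3n (-1.03 ± 0.20) and Tnc (-1.01 ± 0.23). Adjusted p-values of these genes ran from 0.00855 to 0.022 (edgeR). Fmo2 (0.87 ± 0.22), Pde10a (0.81 ± 0.27), Muc3a (0.81 ± 0.23), Fosb (0.75 ± 0.20), Grin1os (0.74 ± 0.21) and the long non-coding RNAs Miat (0.72 ± 0.18), Snhg11 (0.70 ± 0.18) and Meg3 (0.70 ± 0.19) were higher, with adjusted p-values from 0.0149 to 0.0475. Grin1os lies antisense to Grin1, so its reads are uncertain. Synapse and receptor genes had 8 of 18 higher and 10 adjusted over the list alone, median 0.32 (camera adjusted p = 2.14e-05; adjusted p = 0.534 with an estimated correlation). Proliferation genes had 7 of 15 lower and 13 adjusted over the list alone, median -0.56 (camera 1.17e-07; adjusted p = 0.534 with an estimated correlation), and lysosomal Ctsd was lower by -0.52 ± 0.08. Striatum markers had a median of 0.54. The count was 16 with all 72 libraries in 1 fit and 466 with covariates for section position. Without 1 library it went from 1157 (12 h IF16 replicate 3) to 3607 (12 h IF16 replicate 2), with 12 of 36 libraries moving it by over 1.5 times.

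The stroke response of IF12 mice differed from that of AL mice in 2520 genes by the edgeR interaction test, against 4033 by DESeq2. The 10 smallest p-values were those of Pde10a (adjusted p = 0.000274), Mme, Tle4, Lrrk2, Jcad, Dach1, Slmap, Pdpk1, Rarb and Magi2. At 3 h the response of each was lower in IF12 than in AL, by -3.12 ± 0.57 on the log2 scale for Pde10a, -2.48 ± 0.53 for the peptidase Mme and -2.27 ± 0.49 for Dach1. After ischemia alone the same difference was 1.95 ± 0.56 for Pde10a, and at 12 h it was 1.57 ± 0.56 for Pde10a and 1.94 ± 0.52 for Mme. The striatum score moved the same way, at 7.34 in IF12 against 5.59 in AL after ischemia alone, 5.80 against 7.24 at 3 h and 6.93 against 5.38 at 12 h. The hippocampus score moved the other way, at 2.61 against 3.97, 3.02 against 2.23 and 2.94 against 3.56. By stage, 1944 genes differed at 3 h, 720 with a larger and 1224 with a smaller log2 change in IF12, and 2 at 24 h. Ischemia alone, 12 h and 72 h gave 0, with 433, 737 and 1454 at an unadjusted p under 0.05 by edgeR. DESeq2 was run on the interaction as a whole and not by stage. Without 1 library the count ran from 1422 (3 h IF12 replicate 3), 1651 (3 h AL replicate 1) and 1672 (3 h IF12 replicate 2) to 4270 (ischemia alone IF12 replicate 2), and with covariates for section position it was 3858.

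The response of IF16 mice differed from that of AL mice in 49 genes, against 407 by DESeq2, and Lgals3bp, Lgals9 and Grn had the smallest p-values. The response at 72 h was smaller in IF16 by -3.23 ± 0.53 for Ifi30, a lysosomal thiol reductase of antigen-presenting cells, and by -2.37 ± 0.41 for Mpeg1, a pore-forming protein of macrophages. The difference was -2.39 ± 0.45 for Adgre1, which encodes the F4/80 antigen, and -1.96 ± 0.32 for Grn, which encodes the lysosomal protein progranulin. Lgals3bp (-1.63 ± 0.27), Lgals9 (-1.51 ± 0.35), Dhrs1 (-1.10 ± 0.23), Inpp5d (-1.47 ± 0.30), Irf8, a transcription factor of myeloid cells (-1.83 ± 0.36), and Tspo (-1.45 ± 0.37) completed the 10 smallest p-values. By stage, 74 genes differed at 72 h, 1 larger and 73 smaller in IF16, and 0 at the other 4, with 240, 3163, 1958 and 983 genes at an unadjusted p under 0.05 after ischemia alone and at 3, 12 and 24 h. The count was 0 without 72 h IF16 replicate 2 or 3, 5 without 72 h IF16 replicate 1 and 280 without 72 h AL replicate 1. It moved by over 1.5 times without 24 of the 36 libraries, and was 0 with all 72 libraries in 1 fit. For EOD the interaction gave 0 genes, with 771 at an unadjusted p under 0.05 and 23 by DESeq2.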

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

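Among the tests below, those of gene length, of a section taken farther back and the fits with covariates for section position were chosen only after the results were seen, and the intervals over list members, the ratios without 1 library and the look at mitochondrial shares were added after the values were seen.

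The responses to stroke differed between regimens by the interaction test itself in 2520 genes for IF12 and in 49 for IF16. For IF12 the adjusted p-values by edgeR were 0.000274 for Pde10a, 0.000335 for Mme and Tle4, 0.000542 for Lrrk2 and Jcad, 0.00058 for Dach1, 0.000699 for Slmap, 0.000709 for Pdpk1, 0.000734 for Rarb and 0.000891 for Magi2. For IF16 they were 0.00487 for Lgals3bp, Lgals9 and Grn, 0.00937 for Dhrs1, 0.0114 for Ifi30, 0.0235 for Mpeg1, Adgre1 and Inpp5d, and 0.0255 for Irf8 and Tspo. Of 100 drawn splits of the 36 libraries, only the real one gave as many genes for IF12, where the highest other gave 69. Chance is unlikely there only if the libraries of a group are separate animals. For IF16, 18 gave as many, so chance cannot be excluded, and the highest other, with 1495, points to a structure of the samples.

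IF12 and AL differed at 3 h in 1448 genes, with Pde10a among the lower ones. Gene length bias is argued against as the whole cause, since 585 of these genes were still called with each library's length trend removed, at a median absolute log2 difference of 0.57 against 0.75 before and a median SE of 0.19 against 0.23. A section taken farther back in the IF12 brains is a candidate explanation. All 5 hippocampus (median 0.77) and all 8 thalamus markers were above 0 and all 9 striatum markers below 0. With covariates for section position the median was 0.73 with an SE of 0.27 against 0.23 and 0 genes were called. The covariates leave out hippocampus and striatum scores, so this fit cannot decide on position. A gap of 0.6 between thalamus and hypothalamus markers had an interval of -2.28 to 2.06 and decides nothing, and although leaving out 1 library brought the count to 0, this held for 5 of the 6 libraries and so points to no single library. A difference in RNA or library quality, with mitochondrial shares of 3.75 to 4.98% in IF12 against 2.72 to 2.82% in AL, an effect of IF12 feeding, and loss of striatal neurons or of their transcripts at 3 h were not tested apart from section position and stay open.

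IF16 and IF12 differed on average over the stages in 2139 genes, with 8 of 18 synapse and receptor genes higher and 5 of 14 reactive astrocyte genes lower in IF16. Gene length bias is argued against as the whole cause, since 1482 of these genes were still called without the length trend, at a median absolute difference of 0.24 against 0.27. The position of the section stays open, since the thalamus markers exceeded the hypothalamus markers by 0.28 with an interval of 0.05 to 1.16, and 451 of the genes were still called with covariates for section position, at a median of 0.24. Of 100 drawn splits only the real one gave as many genes, so chance is unlikely, again only with separate animals. The highest other gave 879 and points to a structure of the samples. The feeding regimen may have contributed, as a hypothesis, which these tests leave open.

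At 72 h the interaction test gave 74 genes, 73 with a lower log2 change in IF16 than in AL, and Spp1 stood at 11.5 ± 3.14 CPM (n = 3) against 339 ± 449. The numbers of called genes do not settle which response was larger, with 83 in IF16 against 844 in AL but 578 against 312 with only the groups compared, and the 83 became 1 to 7 without any 1 library. Less lesion tissue in the section is a candidate explanation that remains open: the ratio of list medians, IF16 over AL, was 0.12 for proliferation genes (15 tested in AL and 12 in IF16; interval over those in both 0.08 to 0.35, 0.1 to 0.16 without 1 library), 0.19 for activated myeloid genes, 0.5 for interferon-stimulated genes, 0.56 for monocyte and border macrophage genes (9 and 7 tested; 0.16 to 0.99, and 0.36 to 0.86 without 1 library, 72 h IF16 replicate 2 and 72 h AL replicate 3) and 0.56 for meningeal fibroblast genes (0.53 to 1.31, 0.5 to 1.01 without 1 library). Less lesion tissue required under 0.5 in every list, with 0.8 set in advance to exclude it. This rule cannot decide, as log2 changes do not scale with lesion share. Fibroblast and macrophage ratios, above 0.5, passed 0.8 only without 1 library. The highest, 0.91 for autophagy and lysosome, has an interval of -1.11 to 9.5. A different position of the section is open too, with a gap of 0.33 between thalamus and hypothalamus markers (-1.95 to 0.57), and a smaller lesion, less lesion caught in the section and a weaker response of the same tissue cannot be told apart, since no lesion size was analysed here.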

How the results depend on the processing

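The gene length offset, the covariates for section position, the fit of only the groups compared and the library left out of response correlations were chosen only after the results were seen, and the other alternatives were planned. Outside the interactions, whose test has no sign, no named gene changed its sign in an alternative or without 1 library. No called list turned with an estimated correlation, DESeq2 size factors, no filter, the replicate block or all 72 libraries in 1 fit. Without 1 library the response correlation after ischemia alone went from 0.138 to as low as -0.021 for EOD and from 0.082 to -0.079 for IF16, within their jackknife errors, and no other changed its sign. The order of regimens by count did turn. With only the groups compared, AL against IF16 went from 1152 against 2670 to 1261 against 73 at 24 h and from 844 against 83 to 312 against 578 at 72 h, and AL against EOD to 1261 against 3427 at 24 h and 39 against 561 at 12 h. With all 72 libraries in 1 fit AL against EOD turned too, to 623 against 989 at 12 h and 1389 against 2632 at 24 h. With the length offset 99.9% of called genes kept their sign for IF12 at 3 h and for IF16 against IF12 on average. DESeq2 size factors in place of TMM left all 45 counts within 1.5 times and all 15 correlations within their error. Counts moved by over 1.5 times for 34 of 45 comparisons with the DESeq2 test, 23 with all 72 libraries in 1 fit, 20 of 38 with only the groups compared, 13 with section covariates, 11 with the replicate block, 10 with no filter and 6 with the length offset. For the named genes, 54 of 99 lost their call with all 72 libraries in 1 fit, 35 with no filter, 30 with the replicate block, 27 with section covariates, 16 with the length offset and 10 of 45 with only the groups compared, and none with DESeq2 or its size factors. Without 1 library they lost it in 557 fits and kept it in 1597. Unless stated, the cause was not tested for the values that moved.

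With the DESeq2 test, stroke contrasts in AL gave 14 genes after ischemia alone, 123 at 3 h, 843 at 12 h and 1817 at 24 h. Those in EOD gave 4, 83, 778, 1875 and 237 from ischemia alone to 72 h. Those in IF12 gave 57 after ischemia alone and 100 at 12 h, and those in IF16 6 after ischemia alone, 2214 at 3 h, 472 at 12 h and 484 at 72 h. Regimen contrasts for EOD gave 29 in sham, 1 after ischemia alone, 379 at 3 h, 1 at 12 h and 3 at 24 h. Those for IF12 gave 22, 155, 2673, 164 and 123 at the same stages, and those for IF16 2702 in sham, 176 after ischemia alone and 86 at 12 h. Averages gave 8 for EOD, 23 for IF12 and 827 for IF16 against AL, and interactions 23, 4033 and 407.

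With all 72 libraries in 1 fit, stroke contrasts gave 51 at 3 h and 623 at 12 h in AL. In EOD they gave 58, 989, 2632 and 853 from 3 to 72 h, in IF12 1 after ischemia alone and 1 at 12 h, and in IF16 5 after ischemia alone and 23 at 72 h. Regimen contrasts gave 0 at 3 h, 1 at 24 h and 1 at 72 h for EOD. For IF12 they gave 1 after ischemia alone, 16 at 12 h and 48 at 24 h, and for IF16 6 in sham, 1 after ischemia alone and 567 at 72 h. The average of IF16 gave 1 against AL and 16 against IF12, and the EOD and IF16 interactions 1 and 0. With only the groups compared, stroke contrasts in AL gave 3 after ischemia alone, 30 at 3 h, 39 at 12 h and 312 at 72 h. In EOD they gave 5, 40, 561 and 3427 from ischemia alone to 24 h, in IF12 0 after ischemia alone, 12 at 12 h and 1209 at 72 h, and in IF16 12 after ischemia alone, 7 at 12 h, 73 at 24 h and 578 at 72 h. Regimen contrasts gave 3096 at 3 h, 1 at 12 h and 8 at 24 h for IF12 and 3042 after ischemia alone and 152 at 72 h for IF16.

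Replicate numbers in the titles did not pair the libraries: in 0 of 38 contrasts were all 3 correlations of same-numbered libraries above 0.1, and they ran from -0.53 to 0.4. With the replicate block, stroke contrasts gave 3 at 3 h and 120 at 12 h in AL, 1 at 12 h and 502 at 24 h in EOD, 0 at 12 h in IF12, and 0 after ischemia alone and 46 at 12 h in IF16. Regimen contrasts with the block gave 12 for EOD and 3 for IF12 at 3 h and 1261 for IF16 in sham, and the IF16 interaction 7, and the block moved no other count by over 1.5 times.

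With covariates for section position, stroke contrasts gave 9 at 3 h in AL, 21 at 3 h in EOD, and 0 after ischemia alone, 2583 at 3 h and 227 at 72 h in IF16. Regimen contrasts gave 0 at 3 h for EOD, 2 after ischemia alone and 0 at 3 h for IF12 and 1 after ischemia alone for IF16. The averages gave 1309 for IF16 against AL and 466 for IF16 against IF12, and the interactions 3858 for IF12 and 102 for IF16. With the gene length offset, stroke contrasts gave 2 at 3 h and 122 at 12 h in EOD and 52 at 12 h in IF16, regimen contrasts 659 for IF12 at 3 h and 1 for IF16 in sham, and the average of IF16 against AL 47. The offset moved the share of higher calls to 100% at 3 h in EOD, to 33.6% at 12 h in EOD and to 9.6% at 12 h in IF16. With no filter, more genes were tested, and stroke contrasts gave 499 at 24 h in EOD, 5 after ischemia alone and 6 at 12 h in IF12, and 64 at 12 h in IF16. Regimen contrasts then gave 92 in sham and 6 after ischemia alone for IF16 and 1 after ischemia alone and 1 at 24 h for IF12, and the average of IF16 gave 32 against AL and 1366 against IF12.

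Response correlations with no filter, which adds genes with few reads, were 0.101, 0.321, 0.388 and 0.319 from 3 to 72 h for EOD, 0.208, 0.426 and 0.39 from 12 to 72 h for IF12, and 0.121, 0.178, 0.413 and 0.133 from 3 to 72 h for IF16. Over only genes called in AL they were 0.944 at 12 h and 0.929 at 24 h for EOD, 0.863, 0.915 and 0.943 from 12 to 72 h for IF12, and 0.852 at 12 h and 0.61 at 72 h for IF16.

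Leaving out 1 library moved 179 of 480 counts by over 1.5 times. Stroke contrasts ran from 1 to 22 genes at 3 h, 1 to 1347 at 12 h, 267 to 1293 at 24 h and 334 to 1056 at 72 h in AL. In EOD they ran from 0 to 33, 0 to 552, 36 to 664 and 0 to 631 at the same stages. In IF12 they ran from 1 to 38 after ischemia alone, 2473 to 5559 at 3 h, 0 to 0 at 12 h, 4418 to 6726 at 24 h and 1746 to 4886 at 72 h, and in IF16 from 0 to 1, 158 to 1561, 1 to 224, 564 to 3891 and 1 to 7. Regimen contrasts ran from 0 to 456 at 3 h for EOD, 0 to 3 in sham, 0 to 1257 after ischemia alone, 0 to 1343 at 3 h and 0 to 2 at 12 h for IF12, and 0 to 4751 in sham and 0 to 9 at 12 h for IF16. Averages ran from 0 to 5 for EOD, 0 to 26 for IF12 and 2 to 1445 for IF16 against AL and 1157 to 3607 for IF16 against IF12, and interactions from 0 to 2, 1422 to 4270 and 0 to 280 for EOD, IF12 and IF16. Response correlations ran from 0.294 to 0.781 for EOD at 72 h, 0.481 to 0.657 for IF12 at 12 h and 0.614 to 0.811 for IF16 at 24 h. With totals of 16735707 to 24763161 counts, depth limits genes near the floor of 3 counts per library, such as Il1rn and Cd5l in sham, for which only a lower bound of the fold can be given.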

Other observations

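The tests in this part were planned, and the genes, lists and stages described were picked from the planned lists after their values were seen.

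Genes and lists not described so far had called changes in IF12 and IF16 mice. In IF12 at 3 h, the erythrocyte gene Hbb-bs was higher than in sham by 1.20 ± 0.37 on the log2 scale, oligodendrocyte precursor genes had 5 of 7 members lower with a median of -0.79, and heat shock chaperones had 13 of 15 higher and 1 lower with a median of 1.16, led by Hspa1b (6.96 ± 1.12), whose reads cannot be separated from those of Hspa1a. In IF12 at 24 h, heat shock chaperones had 14 of 15 higher, interferon-stimulated genes 18 of 20 with a median of 2.72, and Cxcl10, a chemokine induced by interferon, was higher by 7.78 ± 0.91 (adjusted p = 9.18e-05, edgeR). In IF12 at 72 h, the cystatin Cst7 was higher by 5.73 ± 0.58 (adjusted p = 4.69e-05), 10 of 12 complement genes were higher with a median of 2.34, and Ctsd was higher by 2.07 ± 0.22. In IF16 at 24 h, endothelial cell genes had 5 of 9 higher, among them the tight junction gene Cldn5 (1.40 ± 0.26), and 9 of 12 complement genes were higher with a median of 1.26, with C3 at 2.12 ± 0.29.

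At 3 h, 10 of 17 clock genes were higher and 3 lower than sham in IF12 (camera 0.00433, 0.558 with an estimated correlation). The repressor Nfil3 stood at 3.55 ± 0.37. In IF16, 6 of 17 were higher (camera 0.0665), with Nfil3 at 2.51 ± 0.33. None was called in AL or EOD, with 6 and 3 adjusted over the list alone. Against AL, 1 was higher and 2 lower in IF12 and 0 called in IF16, and the list was not called (camera 0.617 and 0.597). The hour of tissue collection is not in the labels, and no explanation was tested.

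Other splits of the same libraries were counted for each comparison. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In AL, the real split gave 0, 5, 251, 1152 and 844 genes from ischemia alone to 72 h and the highest of the other splits 0, 0, 0, 1 and 1. In EOD these were 0, 9, 6, 933 and 0 against 0 in each, and in IF16 2, 1391, 14, 2670 and 83 against 0, 43, 0, 0 and 0. In IF12 they were 8, 4835, 2, 6677 and 4019 against 1312, 0, 1, 0 and 4, and for ischemia alone 2 of the 10 splits, the real one included, gave as many, which points to a structure of these 6 libraries. For regimens at 3 h, EOD, IF12 and IF16 gave 42, 1448 and 0 genes against 1, 6 and 2 in the highest other split. Where the real split gave 0 genes, all 10 splits gave as many, and other splits gave up to 5344 genes for IF12 in sham, 2483 for IF12 after ischemia alone, 1376 for IF16 at 24 h, 427 for EOD at 12 h, 7 for EOD at 72 h, 2 for IF16 at 3 h, 1 for EOD after ischemia alone and 0 in the others. The 4 largest of these again point to a structure of the samples that the regimens do not explain. For the average of IF16 against AL, only the real one of 100 drawn splits of 36 libraries gave 105 genes and the highest other 27. Chance is unlikely there only if the libraries of a group are separate animals. For the averages of EOD and IF12 and the EOD interaction, with 0 genes, all 100 gave as many. The highest others gave 548, 3 and 2220.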
